A study of Arabidopsis thaliana with 12 samples.

How the data were processed

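Inflorescences of Arabidopsis thaliana, wild type (Col) and amiR-SEAP1 plants, were sampled for mRNA (4 libraries per genotype) and for small RNA (2 libraries per genotype). Plants were grown with 16 h light and 8 h dark at 22 °C, RNA was extracted with Trizol, and small RNA libraries were made from 1 µg of RNA with the TruSeq small RNA kit, per the labels' protocols. The genotype and replicate number of each library were taken from its title.

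The mRNA values were deposited by the authors as FPKM per gene, per the file headers. The submitters' processing notes name HISAT2 and the build TAIR10, with no version. The program that computed FPKM, its annotation and its use of strand are not given in the sources used here. The small RNA values were deposited by the authors as raw counts per mature miRNA, and the files end with count summaries for alignments outside every miRNA. The counter and its annotation are not given in the sources used here. Alignments that fell on no miRNA made up 93.0% and 93.1% of the wild-type and 95.0% and 94.2% of the amiR-SEAP1 small RNA files. With unaligned and ambiguous reads, the lines that name no miRNA held 96.6% to 98.5% of the counts. They stayed out of library sizes and tests, except where the scale is called all alignments, which divides by the sum of every line (63545930 and 72285462 in wild type, 75681831 and 70235819 in amiR-SEAP1).

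The tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That plan assumed mRNA counts and edgeR. Because the values were FPKM, limma was used on log2(FPKM + 1) with a mean-variance trend, for the 20743 genes with a mean of at least 1 FPKM over the 8 libraries, with Benjamini-Hochberg adjustment at an FDR of 0.05. A fold change on this scale understates the change of low genes. DESeq2, size factors and voom weights were therefore not run on the mRNA values, and the comparison of genes with and without introns was not run because no exon annotation was used here. Of the 33610 gene IDs, 28932 matched a locus tag of the RefSeq table of assembly TAIR10.1, which was used for symbols and for overlaps between genes. The other 4678, of which 341 were tested, keep their ID. No coordinates are given.

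The named genes are the 10 with the largest increase and the 10 with the largest decrease among genes past the FDR with a mean of at least 5 FPKM and no overlap between the genotypes (1219 and 802 genes qualified), and up to 4 members of each gene list with the smallest adjusted p. The plan set that mean in CPM, and the same number was used in FPKM. The targeted gene was to be named too, but no symbol or synonym matched SEAP1, and it is not analysed here. Other genes are named only where a list count is small or, in the closing section, where they were chosen after their values were seen. Of the 60 named genes past the FDR, 12 overlap another gene in the reference, and without knowledge of strand their values are uncertain. The 18 lists cover miRNA machinery, miRNA targets, primary miRNA transcripts, trans-acting siRNA loci and their targets, floral identity, tapetum and pollen wall, mature pollen, photosynthesis, cell cycle, splicing factors, salicylate, jasmonate, abscisic acid with cold and drought, heat shock, flavonoid, clock and auxin genes. Lists were tested with camera at its preset correlation, with camera at an estimated correlation and with fry, each adjusted over the lists.

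Small RNA counts were tested with edgeR's quasi-likelihood method with TMM scaling and filterByExpr, per miRNA and per family sum, and named miRNAs are at most the 10 with the largest increase and the 10 with the largest decrease past the FDR with a mean of at least 10 CPM of the miRNA counts. Identical family members share reads: 98 miRNAs fall in 39 groups whose counts lie within 5% or 2 counts of each other, so families are the safer unit. DESeq2, other scalings and other filters were alternatives. The scale of all alignments, 1 member per group that shares reads, the most abundant member of each family, the pair correlation, the means of pairs, the set term, the tests within sets, the same FPKM sum, quantile normalization and the fit without a trend were chosen after seeing the data. Correlations across families used 100000 resamples. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

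The depth of the mRNA libraries is not stated in their values, but steps between low FPKM values give relative depths within a factor of 1.17. Pairs of libraries were checked for repeats of 1 RNA: at 300 to 1000 FPKM times kilobases the coefficient of variation within a pair was 1.45% to 1.73%, and it rose toward 8.89% to 9.31% at 3 to 10, as counting error does. Same-numbered mRNA libraries of the genotypes deviated together from their group means (r = 0.398, 0.420, 0.405 and 0.430). Only 2 of 4 wild-type libraries matched their own number best, so these values show a shared set and not a pairing by number within it. With the replicate number as a block, 2852 genes rose and 2306 fell. Intervals and tests on counts cover counting error and the spread between these libraries only.

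The tests were tried on simulated data. For mRNA, 67 genes were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The shares of false calls depend on these small numbers of changed genes, so they do not carry over to the real calls. With 20743 genes and simulated pairs somewhat more alike than the real ones (fitted pair correlation 0.939 against 0.906), the 8-library test recovered 43.3% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold, and 26.8% of its calls were false. The pair correlation recovered 4.48%, 52.2% and 93.9% with 0 false calls. The simulated pair effects had the same spread in every gene and were independent between genes. Real genes need not be so, and the 0 false calls may not hold for them. The mean of each pair recovered 0%, 0% and 51.5%, also with 0 false calls. With a set term 94.8% of the calls were false, and with the replicate number as a block 76.0%. With 8 independent libraries the 8-library test had 3.80% false calls. The miRNA test on 284 miRNAs recovered 35.7% of those changed 2-fold, 84.6% of those changed 4-fold and 100% of those changed 8-fold, with 2 false calls.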

Results

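RNA from inflorescences of Arabidopsis thaliana was compared between wild-type plants of the Col accession and plants that carry an artificial miRNA against SEAP1 (amiR-SEAP1), to ask how the accumulation of miRNAs and mRNAs differs when SEAP1 is targeted. An artificial miRNA is an engineered small RNA that directs the cleavage of a chosen transcript. The mRNA arm held 8 libraries, 4 per genotype, with 33610 gene IDs given in FPKM, of which 20743 reached a mean of 1 FPKM and were tested. FPKM summed to between 680667 and 715611 per library, and steps between low values put the relative depth of the libraries within a factor of 1.17. The small RNA arm held 4 libraries, 2 per genotype, with counts for 427 mature miRNAs. Counts on miRNAs totalled 2160372 and 2043025 in the wild-type libraries and 1436816 and 1020947 in the amiR-SEAP1 libraries.

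The mRNA libraries formed 2 sets, replicates 1 and 2 and replicates 3 and 4, by the names in the file headers. Within a set, the 2 libraries of a genotype differed by about counting error, with a coefficient of variation of 1.45% to 1.73% for well-covered genes, against 12.7% to 17.7% between the sets of the same genotype. They were therefore counted as 1 sample, so that mean ± SD below is over n = 2 sets per genotype. The first principal component separated the sets (45.1% of the variance) and the second the genotypes (36.0%). The labels do not say that replicates came from separate plants, so p-values measure at most the spread between these samples, which may be technical. Tests that take every library as independent also draw on the smaller noise between the 2 libraries of a genotype in a set. Their SE and p-values for single genes can therefore be too small. No gene symbol or synonym in the reference matched SEAP1, and the targeted gene is not analysed here under that name.

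The number of mRNAs called between the genotypes depended on how the pairs entered the model. In limma's test of the 8 libraries taken as independent, 1556 genes rose and 975 fell in amiR-SEAP1 at an FDR of 0.05, and 79 of the former and 51 of the latter changed at least 2-fold. With a correlation between the libraries of a pair in the model, 48 genes rose and 17 fell, and with the mean of each pair as 1 value limma called 0 in either direction (692 higher and 558 lower at an unadjusted p under 0.05, smallest adjusted p = 0.309). The adjusted p-values and SE of genes below are from the 8-library test unless another is named. MAM1 and CYP79F1, of aliphatic glucosinolate synthesis, were among the 10 named genes that rose most, and no planned list covers that pathway. MAM1, an enzyme of methionine chain elongation, rose from 5.75 ± 0.042 to 30.5 ± 10.997 FPKM (SD, n = 2), and CYP79F1, which makes the aldoximes of that pathway, rose from 2.197 ± 0.294 to 13.1 ± 6.42 FPKM. AT4G05380, an AAA-type ATPase gene, had the largest increase of the named genes in log2(FPKM + 1), from 0.768 ± 0.273 to 10.3 ± 0.265 FPKM. AT2G21640, also known as UPOX, a marker of oxidative stress in mitochondria, rose from 7.22 ± 1.19 to 29.97 ± 2.19 FPKM.

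EMB140, a gene required for embryo development, was lower in every amiR-SEAP1 library than in every wild-type library. It lay at 15.75, 16.2, 15.5 and 14.9 FPKM in the wild-type libraries and at 4.76, 4.55, 4.65 and 4.91 FPKM in the amiR-SEAP1 libraries, a log2 change of -1.53 ± 0.05 (SE, adjusted p = 1.4e-05). No source used here pairs EMB140 with SEAP1 or rules that out, so whether it is the gene that the artificial miRNA targets is left open. The terpene synthase genes TPS14 and TPS10, which are active in flowers, fell from 75.2 ± 16.3 to 26.6 ± 10.1 FPKM and from 88.8 ± 38.7 to 24.7 ± 10.7 FPKM. PCC1, a small gene of the defence and flowering responses, fell from 12.1 ± 1.15 to 2.22 ± 1.78 FPKM, and the beta-amylase gene BAM5 from 203 to 73.9 FPKM. On the log2(FPKM + 1) scale, which understates the change of low genes, MAM1 rose by 2.18 ± 0.19 (SE, adjusted p = 0.000855), CYP79F1 by 2.06 ± 0.25 (adjusted p = 0.00306) and PCC1 fell by 2.14 ± 0.30 (adjusted p = 0.00542).

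The other named genes with large increases were AT2G18193 (log2 change 2.51), AT4G05370 (2.42), AT1G17960 (2.30), AT3G45730 (2.18), SNOR108 (2.05) and THI2.2 (1.99). Those with large decreases were AT1G19960 (-2.55), AT3G27809 (-2.21), AT2G47880 (-1.52), AT3G25810 (-1.51) and AT1G20135 (-1.37). Of these 20 genes, 13 also passed with a correlation of 0.906 between the 2 libraries of a pair in the model. SNOR108 (adjusted p = 0.223 in that model), THI2.2 (0.171), AT1G19960 (0.155), AT3G27809 (0.161), TPS10 (0.0513), AT2G47880 (0.131) and AT3G25810 (0.111) did not. CYP79F1 has a near-identical neighbour, and AT3G27809, AT2G47880 and TPS14 overlap other genes in the reference, so their values are uncertain where reads were split between genes.

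**Figure D1:**
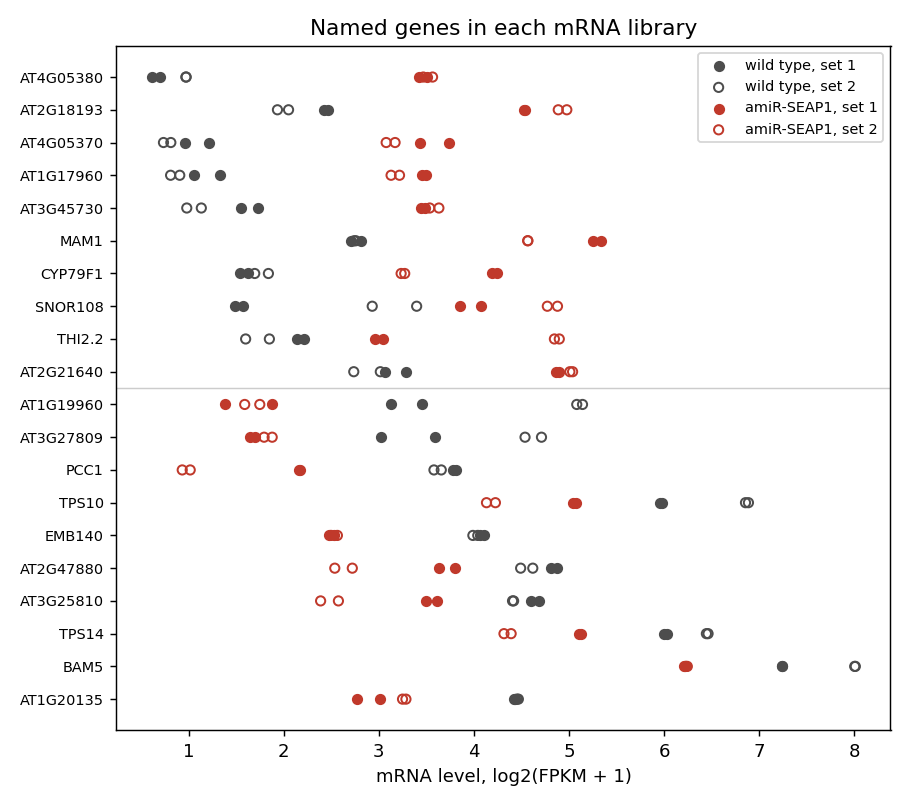
mRNA level of the 10 named genes with the largest increase (top) and the 10 with the largest decrease (bottom) in each of the 8 libraries, as log2(FPKM + 1). Each point is 1 library, filled for set 1 and open for set 2. EMB140 lay between 14.9 and 16.2 FPKM in wild type and between 4.55 and 4.91 FPKM in amiR-SEAP1.

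The counts of the 8-library test also moved with other settings. With the replicate number as a block, 2852 genes rose and 2306 fell. In simulated data this fit made 622 false calls, against 55 in the 8-library test. They were 76.0% of its calls there, a share that depends on how few genes were changed and does not carry over. Leaving out any 1 library lowered the counts, to between 832 and 1173 higher and between 480 and 707 lower. Without replicate 3 or 4 of wild type, or any replicate of amiR-SEAP1, they were between 832 and 947 higher and between 480 and 616 lower.

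Large changes overlapped between the sets more than independent lists of the same lengths would, in the same and, less so, in opposite directions. A change of at least 1.5-fold in both sets was found upward in 206 genes, where independent lists give 22.3, and downward in 199 genes, where they give 47.2. Another 95 genes changed by as much in opposite directions, where they give 65.4. Independent lists may therefore understate the overlap to be had without a shared change, and whether genes that vary more account for this was not tested. Across genes, which are not independent replicates, the log2 changes of the sets had a Pearson r of 0.334 and a Spearman rho of 0.381.

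**Figure D2:**
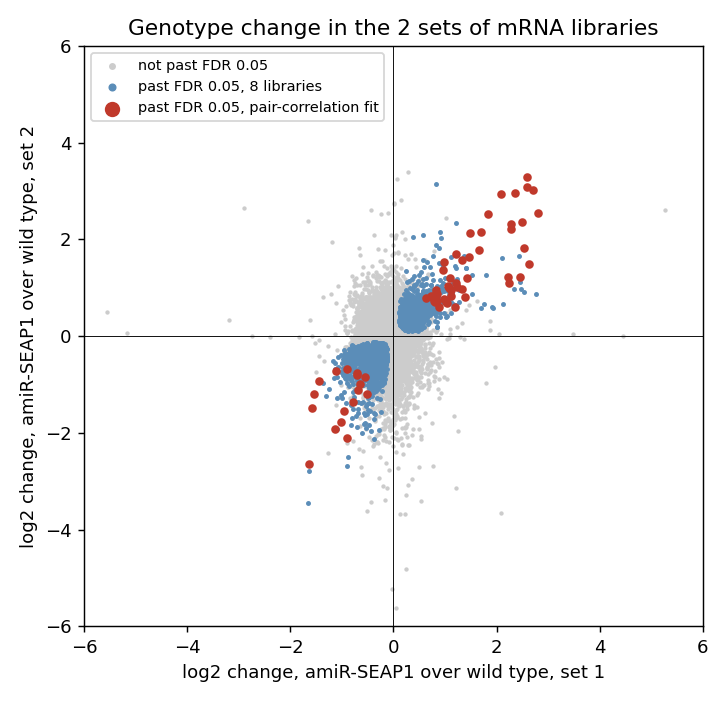
Log2 change of each tested gene (amiR-SEAP1 over wild type) in set 1 (x axis) and in set 2 (y axis). Grey points did not pass an FDR of 0.05, blue points passed in the 8-library test and red points (48 higher, 17 lower) passed with the pair correlation.

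The counts of list members below come from the 8-library test, which takes the libraries of a pair as independent, and most are lost when the pairs are modelled. Of the 430 genes in the 18 lists, that test called 69, whereas with the pair correlation limma called 1 higher, MIR164a, and 1 lower, WRKY54 (33 and 38 at an unadjusted p under 0.05). Unless another setting is named, the SE of list members and the camera p-values also take the libraries of a pair as independent.

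Genes of miRNA production and turnover lay higher in amiR-SEAP1 by small amounts. Of the 41 tested members of this list, 16 rose and 0 fell in limma's test (21 and 0 adjusted over the list alone, and also at an unadjusted p under 0.05). The exonuclease genes SDN2 and SDN3, which degrade miRNAs, rose by 0.52 ± 0.08 and 0.45 ± 0.05 (log2, SE). CBP20, a subunit of the nuclear cap-binding complex, rose by 0.39 ± 0.05, and EMB2765 (MAC7), an RNA helicase gene of the MOS4-associated complex, by 0.31 ± 0.05. The camera test placed the list above other genes (adjusted p = 8.5e-07; adjusted p = 0.289 with an estimated correlation). The list median was 0.13 in set 1 and 0.23 in set 2. Mature pollen genes lay lower (medians -0.40 and -0.27) and photosynthesis genes higher (0.06 and 0.22) in the same sets, and whether a different mix of tissues accounts for the shift was not tested.

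Splicing factor genes moved the same way. Of 33 tested, 8 rose and 0 fell (9 and 0 adjusted over the list alone, 13 and 0 at an unadjusted p under 0.05), among them RS2Z32, an SR protein gene (0.37 ± 0.05), SR34b (0.37 ± 0.08), SUS2, which encodes the spliceosome core protein PRP8 (0.32 ± 0.07), and SC35 (0.22 ± 0.05). The camera adjusted p was 1.04e-04 (adjusted p = 0.289 with an estimated correlation). RS2Z32, SC35 and SDN3 overlap other genes in the reference, as do MYC2, DREB2A, STK, BOA and PRL, which are named below. Mitotic and replication genes rose in 3 of 24 cases and fell in 0 (3 and 0 adjusted over the list alone, 9 and 1 at an unadjusted p under 0.05). MCM5, a subunit of the replicative helicase, rose by 0.42 ± 0.06. The camera adjusted p of this list was 0.0145 (adjusted p = 0.390 with an estimated correlation), but 0.0685 without wild-type replicate 1 and 0.0566 without wild-type replicate 2. Of 31 photosynthesis genes, markers of green tissue, 1 rose, LHCB2.2 (0.42 ± 0.11), and 0 fell (0 and 0 adjusted over the list alone, 7 and 0 at an unadjusted p under 0.05). Their camera adjusted p was 0.00390 (adjusted p = 0.326 with an estimated correlation).

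**Figure D3:**
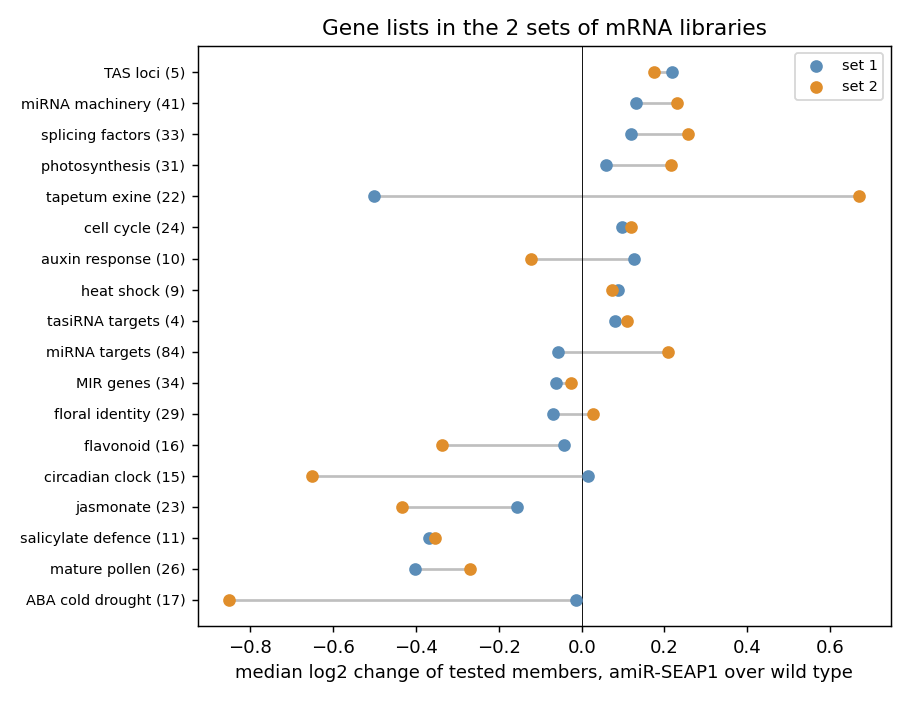
Median log2 change (amiR-SEAP1 over wild type) of the tested members of each gene list in set 1 (blue) and set 2 (orange), with the number of tested members in brackets. The medians of the tapetum list were -0.50 in set 1 and 0.67 in set 2, and those of the miRNA machinery list were 0.13 and 0.23.

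Genes of mature pollen lay lower in amiR-SEAP1. Of 26 tested, 6 fell and 0 rose (7 and 0 adjusted over the list alone, 8 and 0 at an unadjusted p under 0.05). The actin-depolymerizing factor gene ADF7 fell by 0.52 ± 0.07 (log2, SE), the profilin gene PRF4 by 0.51 ± 0.09 and PPME1, a pectin methylesterase gene of the pollen tube, by 0.39 ± 0.10. The camera adjusted p was 1.04e-04 (adjusted p = 0.326 with an estimated correlation), with medians of -0.40 in set 1 and -0.27 in set 2. Tapetum and pollen wall genes, which mark earlier anther stages, had medians of -0.50 and 0.67 in the same sets.

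Hormone and stress response genes were mixed. Of 23 jasmonate genes, 2 rose and 4 fell (2 and 10 adjusted over the list alone). MYC2, the main transcription factor of the response, fell by 0.53 ± 0.10 and the synthesis gene AOS by 0.42 ± 0.07, whereas AOC1, also of jasmonate synthesis, rose by 1.35 ± 0.18. The camera adjusted p was 9.6e-04 downward (adjusted p = 0.326 with an estimated correlation). Of 17 abscisic acid, cold and drought genes, 3 fell and 0 rose (4 and 1 adjusted over the list alone, 7 and 1 at an unadjusted p under 0.05), namely KIN1 (-0.63 ± 0.16), ERD10 (-0.70 ± 0.17) and DREB2A (-0.88 ± 0.16). This list had a camera adjusted p of 5.6e-04 downward (adjusted p = 0.326 with an estimated correlation), and its median was -0.01 in set 1 and -0.85 in set 2. Of 11 salicylate defence genes, 3 fell and 1 rose (4 and 1 adjusted over the list alone). WRKY54 fell from 4.39 to 0.862 FPKM and NIMIN1, a regulator of NPR1, from 15.69 to 6.02 FPKM, while SAG101 rose by 0.42 ± 0.08. The camera adjusted p was 0.0241 downward (adjusted p = 0.289 with an estimated correlation; 0.0559 with the replicate number as a block). Of 16 flavonoid genes, 0 passed in limma's test over all genes or adjusted over the list alone (3 lower and 0 higher at an unadjusted p under 0.05), although the list had a camera adjusted p of 0.0145 downward (adjusted p = 0.289 with an estimated correlation). No list call held with an estimated correlation. With camera at its preset correlation on the mean of each pair, 9 of 9 list calls held.

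Transcripts that miRNAs target were not called as a group. Of 84 tested, 10 rose and 1 fell (10 and 1 adjusted over the list alone), and the camera adjusted p was 0.400. Those that rose included SPL2, a target of miR156 (0.62 ± 0.09), the growth regulator genes GRF1 (0.45 ± 0.11), GRF2 and GRF8 of miR396, the auxin receptor genes TIR1 (0.27 ± 0.05) and AFB2 of miR393, and SULTR2;1, a sulphate transporter gene of miR395 (0.47 ± 0.05). NF-YA2, a target of miR169, fell by 0.61 ± 0.17. Among 34 primary miRNA transcripts, 1 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.306). MIR171b fell by 0.74 ± 0.11, MIR172b by 0.84 ± 0.16 and MIR162a by 0.45 ± 0.08. MIR164a rose from 0.110 to 4.26 FPKM. Of 5 tested trans-acting siRNA loci, 1 rose and 0 fell (2 and 0 adjusted over the list alone, and also at an unadjusted p under 0.05; camera adjusted p = 0.392). TAS1A was the locus that rose (0.30 ± 0.08). Of the 4 tested genes that such siRNAs target, 0 passed limma's test over all genes and 1 rose adjusted over the list alone, the same gene as at an unadjusted p under 0.05 (ETT, 0.23 ± 0.07; camera adjusted p = 0.559).

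The remaining lists were not called. Of 29 floral identity genes, SEP4 rose by 0.25 ± 0.06 and STK, an ovule identity gene, fell by 0.51 ± 0.11, with the same counts adjusted over the list alone (camera adjusted p = 0.152). Of 15 clock genes, 1 fell, BOA (-0.55 ± 0.14), and 0 rose, while 2 fell and 1 rose adjusted over the list alone, and 4 and 2 did at an unadjusted p under 0.05 (camera adjusted p = 0.370). Of 10 auxin response genes, IAA19 alone fell (-0.57 ± 0.07), also adjusted over the list alone, and the camera adjusted p was 0.717, downward although the median was 0.11 and the mean 0.03. Of 9 heat shock genes, 0 passed limma's test, also adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05 (camera adjusted p = 0.559). Of 22 tapetum and pollen wall genes, 0 passed limma's test or did so adjusted over the list alone, and at an unadjusted p under 0.05 there were 1 higher and 2 lower. Their camera adjusted p was 0.907, downward although the median was 0.13 and the mean 0.06.

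miRNAs took a smaller part of the small RNA alignments in amiR-SEAP1. They held 33997 and 28263 CPM of all alignments in the wild-type libraries and 18985 and 14536 in the amiR-SEAP1 libraries, or 31130 ± 4054 against 16760 ± 3146 (SD, n = 2, exact two-sided permutation p = 0.333, the smallest that 2 against 2 libraries allow), a ratio of 0.538. The miR165 and miR166 family, which targets the HD-ZIP III transcription factors, made up 61.1% to 68.7% of the miRNA counts as deposited, in which near-identical members hold nearly the same counts. With 1 member per group that shares reads it made up 28.1% to 33.9%, and the ratio of all miRNAs was 0.568. Without the family the ratio was 0.606.

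Relative to the other miRNAs, few miRNAs were called as changed with 2 libraries per genotype. In edgeR's quasi-likelihood test with TMM scaling, 14 of 294 miRNAs rose and 1 fell. With the replicate number as a block the test called more in both directions, with counts given under the dependence on processing. miR843 rose most, from 0.990 ± 0.069 to 11.9 ± 0.051 CPM of all alignments (n = 2, log2 change 4.28, adjusted p = 0.00113). miR397b (4.01), miR397a (2.15) and miR408-3p (2.01), which target laccase and plantacyanin transcripts, miR398b-5p (2.27) and miR398c-5p (2.25) rose as well, as did miR773a (3.40) and the members a, d and e of miR854. miR398b-5p and miR398c-5p held nearly the same counts, 9 to 35 per library, and miR854d and miR854e held the same counts, 7 to 30. The more abundant miR398b-3p and miR398c-3p did not pass (edgeR adjusted p = 0.111). miR390b-3p fell from 103 ± 22.9 to 20.3 ± 3.69 CPM of all alignments (log2 change -1.63, adjusted p = 0.0317). The 1 decrease was lost without wild-type replicate 1, wild-type replicate 2 or amiR-SEAP1 replicate 2, and 7 miRNAs fell without amiR-SEAP1 replicate 1. The 14 increases became 0 without either wild-type replicate and 3 without amiR-SEAP1 replicate 2, and edgeR's unadjusted p was under 0.05 for 36 higher and 17 lower miRNAs in the full test.

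Scaled to all alignments, the split of the calls turned. The median log2 change of the miRNAs was 0.00 with TMM, 0.22 with the total miRNA count and -0.70 with all alignments. On the last scale 13 of 295 miRNAs rose and 52 fell, and with 1 member per group that shares reads 13 of 240 rose and 78 fell. Of the 295, 83.7% lay below wild type, against 50% with TMM and 34.7% with the total miRNA count.

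Of the 24 families with listed targets, miR397 and miR408 rose on both scales, and 9 families fell on the alignment scale. miR397 went from 0.609 ± 0.118 to 2.44 ± 0.400 CPM of all alignments (n = 2, log2 change with TMM 2.70, adjusted p = 0.000747; on the alignment scale 2.00, adjusted p = 0.0120). miR408 went from 10.7 ± 3.64 to 24.8 ± 1.06 (1.94, adjusted p = 0.00540; 1.22, adjusted p = 0.0255). miR168, which targets AGO1, went from 624 ± 41.3 to 221 ± 12.8 CPM of all alignments (-1.50 on the alignment scale, adjusted p = 0.0120; -0.80 with TMM, adjusted p = 0.0883). miR396, which targets GRF genes, went from 136 ± 2.77 to 50.8 ± 2.36 (-1.42, adjusted p = 0.0120; -0.72 with TMM, adjusted p = 0.148). The families miR156 and miR157 (-0.86), miR163 (-0.97), miR164 (-0.95), miR170 and miR171 (-0.97), miR172 (-1.0002), miR393 (-0.90) and miR824 (-1.05) also fell on the alignment scale, and with TMM these values were between -0.17 and -0.35. miR159, miR167, miR169 and miR403 lay above wild type with TMM and below it on the alignment scale. miR394 differed more between replicates than between genotypes, at 162 and 17.9 CPM of all alignments in wild type and 71.7 and 8.87 in amiR-SEAP1. So did miR160, at 704 and 182 in wild type and 266 and 67.2 in amiR-SEAP1. In both families replicate 1 was the higher in each genotype, and amiR-SEAP1 was lower within each replicate number. Neither family was called on either scale with the replicates taken as independent. Over all 136 families tested with TMM, edgeR called 7 higher and 0 lower (17 and 10 at an unadjusted p under 0.05; DESeq2 called 10 and 2), and on the alignment scale it called 6 and 42 of 140. The 7 higher families were miR397, miR408, miR773, miR843, miR852, miR854 and miR857, and they became 0 without wild-type replicate 2, 4 without amiR-SEAP1 replicate 1 and 3 without amiR-SEAP1 replicate 2.

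**Figure D4:**
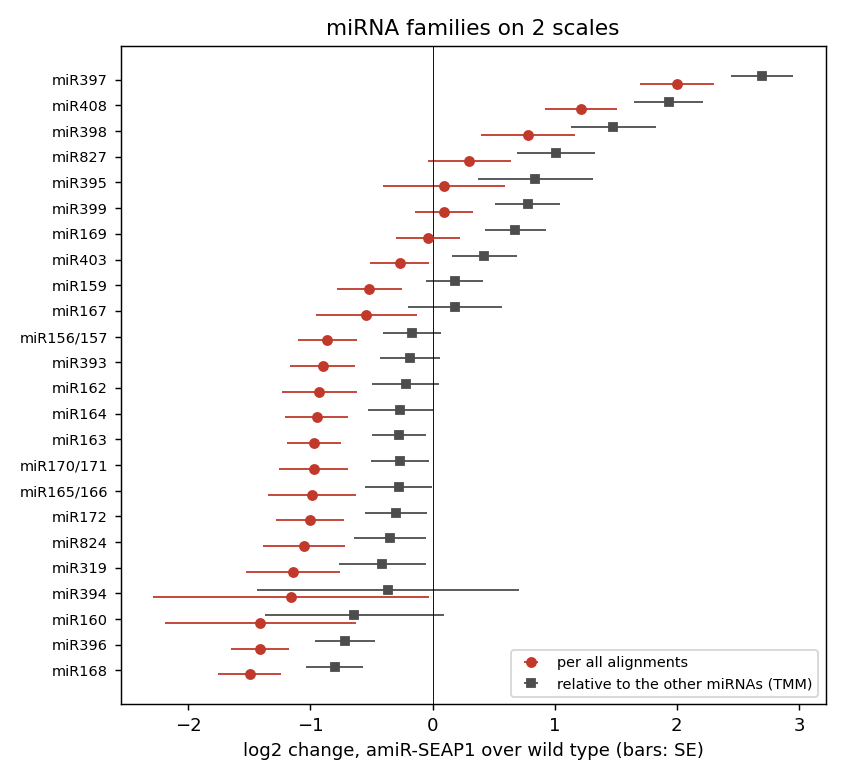
Log2 change (amiR-SEAP1 over wild type, bars: SE of the fit, 2 libraries per genotype) of the 24 miRNA families with listed targets, relative to the other miRNAs (black squares, TMM) and to all alignments (red circles). On the alignment scale 18 families lay below 0 and 6 above, and with TMM 14 lay below 0.

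No relation of the family changes with those of their targets was detected. Across 23 families with a tested target, which are not independent replicates, the median log2 change of the targets had a Pearson r of -0.173 (permutation p = 0.432) and a Spearman rho of -0.073 (permutation p = 0.740) with the TMM change of the family. Without miR397 and miR408, the farthest families, r was 0.038 (permutation p = 0.870). Targets of miR396 had a median of 0.32, with 3 of 7 higher, and those of miR165 and miR166 a median of 0.25, with 1 of 5 higher (ATHB-15, 0.38 ± 0.05). AGO1, the target of miR168, had a log2 change of 0.01. Other families moved in the same direction as the median of their targets. Among them were miR164 (-0.26 with TMM, targets -0.20), miR170 and miR171 (-0.27, targets -0.13) and miR395 (0.84, targets 0.30).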

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

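The tests on splits of the libraries, on repeats within pairs, on flower stages, on miR165 and miR166 and on dilution were chosen after the results they bear on were seen, whereas those on depth and on plant line or batch were set before.

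The first pattern is the 2531 genes that differed between the genotypes in the 8-library test. Of the 35 splits of the 8 libraries, 2 gave as many genes, the real one and the split by library set, which gave 5690, so chance is not excluded by this count and the samples have a structure of their own. Of the other splits, the one that crosses the pairs gave 40 and the remaining 32 at most 1. Each of these 32 parts near-repeat libraries, so few calls were assured and they say nothing on the genotypes. Among the 8 splits that part all 4 numbered pairs, the highest other gave 40, again the split that crosses the pairs. The rest of the 8 also part near-repeat libraries. Within a pair, the largest coefficient of variation was 1.73% for well-covered genes, as repeats of 1 RNA sample would give. This leaves 2 samples per genotype. With the pair correlation 65 genes passed. That fit recovered 93.9% of 4-fold changes in simulated data with 0 false calls, but there the pair effects of every gene had the same spread. The 0 false calls therefore do not carry over to the 65 genes. With limma on the mean of each pair 0 genes passed, and 692 higher and 558 lower had an unadjusted p under 0.05.

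The second pattern is that the genotype difference was unlike in the sets, with 8907 genes past an FDR of 0.05 for the difference itself, but each set holds 1 sample per genotype, so this test sets samples against the noise between near-repeat libraries and many calls were assured. By gene list and against the same noise, camera's adjusted p was 3.59e-14 for tapetum and pollen wall genes, 1.93e-08 for abscisic acid, cold and drought genes, 1.43e-04 for jasmonate genes, 4.34e-04 for flavonoid genes, 0.00398 for photosynthesis genes and 0.0141 for miRNA targets, and with an estimated correlation it was 0.0483 for the first 2 and 0.0572, 0.0625, 0.483 and 0.148 for the others. Sequencing depth is not a cause by its test, since relative depths differed by a factor of 1.17 at most. A different mix of flower stages stays open: the tapetum genes moved by 1.07 (log2) more in set 2 than in set 1, outside the central 95% of random lists (-0.18 to 0.12), as did photosynthesis (0.172; -0.240 to -0.0164) and floral identity genes (0.134; -0.0909 to 0.129) but not mature pollen (0.128; -0.108 to 0.138) or cell cycle genes (0.0378; -0.0705 to 0.139), yet the tapetum genes were examined because they had shown this difference, and random lists lack the correlation within a list. Plant line and growth batch cannot be told apart from the set, because each set holds 1 sample per genotype.

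The third pattern is the smaller share of miRNAs among small RNA alignments in amiR-SEAP1, a ratio of 0.538. The dominant family is not its whole cause, since the ratio without miR165 and miR166 was 0.606. Dilution by other alignments stays open and cannot be told apart from lower miRNA levels: it would lower every family alike, and the listed families lay -0.27 (log2) from 45 families with numbers of 5000 or higher (permutation p = 0.0903), of which 43 also lay below wild type. Alignments outside every miRNA made up at least 94.2% of the amiR-SEAP1 libraries and at most 93.1% of the wild-type libraries, and what they hold is not analysed here. A biological cause, the targeting of SEAP1, was not tested apart from these.

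A library stood apart from the others of its group in 2 of 124 groups examined, by the gap over the range. About 1 in 20 groups of 4 independent values would pass this cut. Libraries in near-repeat pairs pass it less readily, so the count cannot be set against that rate. ATHB-15 lay at 19.9 FPKM in wild-type replicate 2 against 18.17 to 18.43 in the others (gap over range 0.842). PRL, which encodes MCM7, lay at 30.2 FPKM in amiR-SEAP1 replicate 1 against 32.4 to 32.7 in the others (0.882).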

How the results depend on the processing

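The pair, set, FPKM sum, quantile, trend, shared-read, most abundant member and all-alignment settings were chosen after seeing the data. The mRNA counts (1556 higher, 975 lower) stayed within 1.5 times with a pseudocount of 0.1 or 0.01, no filter, the same FPKM sum, quantile normalization and no trend. They were 79 and 51 at least 2-fold, 2852 and 2306 with the replicate block, 48 and 17 with the pair correlation, 4676 and 3786 with a set term, 4709 and 5050 in set 1 alone, 7644 and 5428 in set 2 alone, and 0 and 0 with limma on the mean of each pair (692 and 558 at an unadjusted p under 0.05) or with a set term added (1442 and 1485). The set term and the tests within a set measure samples against the noise between near-repeat libraries. With 1 library left out the counts ranged from 832 to 1173 and from 480 to 707. The cause of these shifts was not tested.

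With an estimated correlation no list call held: adjusted p was 0.289 for miRNA machinery, splicing factors, flavonoid and salicylate genes, 0.326 for mature pollen, photosynthesis, jasmonate and abscisic acid genes and 0.390 for cell cycle genes. fry, which tests a list against no change and not against the other genes, gave 0.0583 for abscisic acid and 0.0658 for jasmonate genes, but 0.0403 for floral identity and 0.0114 for trans-acting siRNA loci. The replicate block ended the salicylate call (0.0559) and no other list call. Camera on the mean of each pair, still with the preset correlation, kept 9 of 9 list calls. Its adjusted p ranged from 3.26e-05 for miRNA machinery to 0.0403 for cell cycle genes. Cell cycle genes ranged from 0.00443 to 0.0685 with 1 library left out. Primary miRNA transcripts (0.652) and tapetum genes (0.870) were upward in fry and downward in camera, which need not be a turn because the tests differ in what they compare with. In camera the direction turned for tapetum genes with no filter (0.952), the mean of each pair (0.909) and without replicate 1 or 2 of either genotype (0.334 to 0.777 with any 1 library left out). The cause was not tested.

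For miRNAs (14 higher, 1 lower), same-numbered small RNA libraries deviated together from their group means (r = 0.521), but 2 libraries per genotype give only this 1 value. Whether the numbers pair the small RNA samples is left open, and the block gave 38 and 14. All alignments gave 52 lower, or 78 with 1 member per group that shares reads, the total miRNA count 0 lower (5 at an unadjusted p under 0.05 in edgeR), and 1 library left out 0 to 16 higher and 0 to 7 lower. Families (7 higher, 0 lower) were 17 and 11 with the block, 11 and 4 with no filter, 2 lower with DESeq2, 42 lower with all alignments, and 0 to 8 higher and 0 to 1 lower with 1 library left out. The share of miRNAs below wild type was 34.7% with the total miRNA count and 83.7% with all alignments. Log2 changes of families turned with all alignments for miR159 (-0.52), miR167 (-0.54), miR169 (-0.0364) and miR403 (-0.27), with the total miRNA count for miR156 and miR157 (0.0567), miR162 (0.0298) and miR393 (0.0153), and with the most abundant member for miR169 (-0.86). With 1 library left out they ranged from -2.01 to 0.52 for miR160, -0.45 to 0.0395 for miR162, -0.47 to 0.64 for miR167, -0.78 to 0.0309 for miR319, -0.36 to 0.00318 for miR393 and -2.61 to 1.82 for miR394. The correlation of families with targets was 0.038 without the 2 farthest families. None of these families was called with TMM, and the cause was not tested. Low counts limit miR397, miR857, the named miR854 members, miR398b-5p and miR398c-5p, and FPKM under about 1 limits the mRNA folds.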

Other observations

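The lists for glucosinolate, mitochondrial stress, terpene synthase and copper genes were made after the leading genes had been seen. Each was tested only on members other than those leading genes, called members not seen before. They were measured in the same libraries, so these tests are not independent of the leading genes. AT5G51440, counted as not seen before, was itself among the calls with the pair correlation, as AOX1A, CRF6 and NAC13 were. The test on MIR164a was chosen after its result was seen.

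Several genes of aliphatic glucosinolate synthesis were higher in amiR-SEAP1 in the 8-library test. Of 12 tested members not seen before, 8 rose and 0 fell in that test, while with the pair correlation the smallest adjusted p among them was 0.0601 (SUR1). They include CYP83A1 (log2 change 1.26 ± 0.24, SE), the sulfotransferase gene SOT17 (1.197 ± 0.13), SUR1 (0.64 ± 0.07), UGT74C1 (0.67 ± 0.09) and the regulator MYB29 (1.40 ± 0.29), while MYB28 had a change of 0.04 ± 0.18. BAT5, a bile acid transporter family gene of the chloroplast, rose from 3.80 ± 1.32 to 14.7 ± 3.25 FPKM (SD, n = 2 sets), and AKN2, which supplies activated sulphate, from 12.5 ± 2.42 to 27.7 ± 3.18. The increases were larger in set 1 than in set 2, with list medians of 0.81 and 0.49.

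Some genes of the mitochondrial retrograde response, which follows disturbed respiration, were higher and others lower. The alternative oxidase gene AOX1A rose from 15.1 ± 1.06 to 46.3 ± 7.04 FPKM (SD, n = 2 sets), the transcription factor genes CRF6 and NAC13 from 12.2 ± 1.37 to 34.9 ± 0.271 and from 8.89 ± 1.38 to 21.1 ± 1.45, and each passed with the pair correlation (limma adjusted p = 0.00164 for CRF6, 0.0331 for NAC13 and 0.00232 for AOX1A). Of 12 members not seen before, 6 rose in the 8-library test, among them AT5G51440, which encodes a mitochondrial heat shock protein (1.81 ± 0.19) and was the 1 member to pass with the pair correlation (adjusted p = 0.0324), NDB4 (0.87 ± 0.10) and NDA1 (0.67 ± 0.09), and 2 fell, AOX1B (-0.57 ± 0.10) and GSTU24 (-0.34 ± 0.08).

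Hypothesis: the whole aliphatic glucosinolate pathway may be higher in amiR-SEAP1. On the members not seen before, camera gave p = 6.02e-08 (limma's camera, upward; adjusted p = 2.41e-07), but 0.0791 with an estimated correlation.

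Hypothesis: a wider mitochondrial stress response may be present. Camera gave 0.0259 on the members not seen before (upward; adjusted p = 0.0517 over the 4 lists), and 0.197 with an estimated correlation, so the correction ends the call.

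Hypothesis: floral terpene synthases may be lower as a group. Camera gave 0.0482 on 4 members not seen before (downward; adjusted p = 0.0636), and 0.246 with an estimated correlation. TPS11 fell by 0.56 ± 0.07, and TPS21 (-1.51 ± 0.46), TPS03 (-1.44 ± 0.74; 0.54 in set 1, -3.42 in set 2) and TPS02 (0.71 ± 0.28; 1.24 and 0.19) did not pass, so the members go both ways. The list median was -0.01 in set 1 and -1.45 in set 2.

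Hypothesis: a response to limited copper might lie behind the increase of miR397, miR408 and miR857, which act on copper proteins. The miR398 family, which belongs to that response, did not pass (adjusted p = 0.0568 with TMM, 0.144 on the alignment scale). The list of other genes did not pass either (camera adjusted p = 0.0636, the same unadjusted, in the direction opposite to the prediction, and 0.379 with an estimated correlation), with medians of 0.27 in set 1 and -0.69 in set 2. Of its 8 tested members, 0 rose and 2 fell in the 8-library test, the copper transporter gene COPT1 (-0.62 ± 0.06) and FRO3 (-0.54 ± 0.14). FSD1, which is induced when copper is low, had a change of 1.05 ± 0.32 that did not pass. The members disagree, and the explanation stays open.

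Hypothesis: reads of an artificial miRNA transgene built on the MIR164a precursor could account for the MIR164a transcript, which went from 0.110 ± 0.063 to 4.26 ± 0.494 FPKM (SD, n = 2 sets). Such a transgene would raise the precursor without the mature miRNA, and the miR164 family changed by -0.26 (log2, TMM) and -0.95 on the alignment scale. The labels used here do not name the precursor of the artificial miRNA. The family sum pools the miR164 members, so it does not show the product of MIR164a alone. Lower processing of MIR164a was not tested and cannot be told apart by these values. Of the 34 primary miRNA transcripts tested, 1 rose, MIR164a, and 5 fell in the 8-library test.

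Within pairs, 18 genes with a mean of at least 5 FPKM differed more than 4-fold in FPKM + 1 between libraries that otherwise differed by counting error. CTH, chosen after its values were seen, was at 46.2, 49.9, 0.038 and 40.4 FPKM in the amiR-SEAP1 libraries and between 0.018 and 0.601 FPKM in wild type.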
